A study of Zea mays with 12 samples.

How the data were processed

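Gene expression was measured in cortex cells cut by laser microdissection from maize primary roots (inbred line B73), in a segment of 0.5 cm that began 1.5 cm and ended 2 cm away from the point where shoot and root meet. Seedlings were grown at 28 °C for 3 days. Per the labels' protocols, 1 set of roots was kept aerated, 1 set was waterlogged for 12 hours, and 1 set received 1-methylcyclopropene (1-MCP, a gas that blocks ethylene perception) at 1 ppm for 12 hours before waterlogging. Labelled RNA of 2 treatments was hybridised together on each of 12 Agilent 2-colour oligonucleotide arrays. There were 2 comparisons, waterlogged against aerated and 1-MCP and waterlogged against waterlogged, each with 3 biological replicates per the labels, and each replicate was hybridised once in a first dye orientation and once with the colours swapped. The labels do not say whether the waterlogged RNA of a replicate was the same extract in both comparisons. No 1-MCP-treated aerated roots are among the samples.

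The deposited scanner files hold the spot intensity of each channel on a linear scale, with local background, as written by Agilent Feature Extraction 10.5.1.1 per the submitters' processing notes. The same files hold the log10 ratio of Cy5 over Cy3 that Feature Extraction computed, per the file headers. The authors' deposited value table also holds log10 ratios. Set against the scanner files, it held the Feature Extraction log10 ratio to within 5e-06, with the sign turned on first-orientation arrays, so that its columns run as aerated over waterlogged and as 1-MCP and waterlogged over waterlogged. Its column medians were 0, with no further scaling or centring found. Each array carried 43451 spots, of which 1417 were controls and 42034 were probes with 1 spot each.

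From the scanner intensities, the background was corrected with normexp (offset 50, mean foreground and median local background) and log2 ratios were normalised within each array by loess, with control spots and the 54 spots marked as outliers over all arrays given no weight and then left out (limma 3.58.1, R 4.3.3). The direction of every ratio was taken from the dyes in the labels. Ratios were turned to waterlogged over aerated and to 1-MCP and waterlogged over waterlogged, and an array and its colour swap were averaged, so that n = 3 per comparison. Each of the 12 arrays correlated best with its own swap. A probe was tested where, in at least 1 comparison, 1 of the RNAs was well above background on at least 5 of 6 arrays, which kept 13022 probes and left out 29012. Both comparisons entered 1 limma fit with 4 residual degrees of freedom and 1 spread per probe. Calls were two-sided, at a Benjamini-Hochberg adjusted p under 0.05. The contrast of 1-MCP and waterlogged against aerated was the sum of both coefficients and was not hybridised directly. Counts are of probes. Taking the brightest probe of each of the 12709 tested identifiers gave 2637 called with waterlogging and 4659 with 1-MCP. Among identifiers with 2 or more called probes, the signs disagreed in 3 with waterlogging and in 5 with 1-MCP.

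No spot was saturated. Between 24.2% and 36.6% of probes were well above background in a channel (10164 to 15401 probes), and the number of arrays limits the precision. The fit was tested on simulated data over 13005 probes with 200 changed probes per comparison. It recovered 55.3%, 95.9% and 99.5% of changes of 0.5, 1 and 2 on the log2 scale for waterlogged against aerated, and 54.3%, 95.1% and 99.6% for the 1-MCP comparison. Of its calls, 5.74% for waterlogging and 6.39% for 1-MCP were of unchanged probes, against a nominal 5%. Both comparisons were simulated with the same spread per probe, so the 2 sets of figures are draws of 1 setting. The real median SDs between replicates were 0.162 for waterlogging and 0.131 for 1-MCP, and far more probes were called. The simulated shares therefore do not give the power or false share of each real comparison.

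Probes carry assembly or sequence identifiers, and no description other than "Unknown". Of 39174 identifiers, 2 matched the supplied gene table (assembly Zm-B73-REFERENCE-NAM-5.0), and 23 probes carry a name in the files. None of the 30 gene lists fixed in advance, including the markers of other root cell types, had a matched identifier, so the planned list tests were not run. The rule for named genes (the 10 largest rises and falls past the threshold with 1 sign on all 6 arrays) needed gene names. In its place, the text gives every tested probe that the files or the gene table name, and the 2 identifiers per direction and comparison with the largest change that met the other conditions of the rule.

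The design, the comparisons and these alternatives were fixed before the data were examined: Agilent's processed signals, no background subtraction, median centring, scaling between arrays, other filters on dim probes, 12 arrays with a dye term, a single dye orientation, each comparison fitted alone, eBayes with trend and robust, the replicate number as a block, separate channels, slides, the authors' value table, each replicate left out, a 2-fold minimum and the median over a gene's probes. A normexp offset of 10, centring on the spike-in controls, leaving out the colour swap of waterlogged against aerated replicate 2, and setting 1-MCP and aerated channels against each other across arrays (quantile-normalised mean signals) were chosen after seeing the data. The arrays lay on 4 slides, and all arrays of a slide had the same dye orientation. A pair of slides held both comparisons (waterlogged against aerated replicate 3 and all 1-MCP replicates), and the other pair held waterlogged against aerated replicates 1 and 2.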

Results

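The arrays compared cortex cells of aerated, waterlogged, and 1-MCP-treated waterlogged maize roots, in the setting of lysigenous aerenchyma, the gas space that forms when cortex cells die. Waterlogged RNA was measured against aerated RNA and against RNA of waterlogged roots treated with 1-MCP, with n = 3 replicates per comparison and each replicate the mean of 2 arrays of opposite dye orientation. The mean share of probes well above background was 28.3% ± 3.97 (SD, n = 3) in waterlogged and 32.1% ± 3.40 (SD, n = 3) in aerated RNA of the first comparison. In the second it was 28.7% ± 1.16 (SD, n = 3) in waterlogged and 31.4% ± 2.29 (SD, n = 3) in 1-MCP-treated RNA. Across probes, which are not independent replicates, the log2 ratios of replicates correlated at r = 0.70 to 0.77 for waterlogging and at r = 0.87 to 0.91 for 1-MCP.

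The first comparison asked which transcripts of the cortex change with 12 hours of waterlogging. Of 13022 probes, 2694 changed, 1195 of them upward and 1499 downward (limma, Benjamini-Hochberg). The probe of TC279794 rose 91.8-fold (log2 waterlogged over aerated 6.52 ± 0.48, SD, n = 3; limma adjusted p = 1.69e-05), and that of TC310712 rose 63.2-fold (5.98 ± 0.87, SD, n = 3; limma adjusted p = 0.000219). The probe of TC286836 fell 15.5-fold (log2 -3.95 ± 0.64, SD, n = 3; limma adjusted p = 0.000926), and that of TC301530 fell 12.3-fold (-3.62 ± 0.05, SD, n = 3; limma adjusted p = 0.000219). With scaling between arrays these 4 probes lost their call (limma adjusted p = 0.0602 to 0.106), while their log2 ratios were 12.52, 11.03, -6.15 and -7.07. The files do not pair these identifiers with gene names. The 60-base probe of TC279794 reads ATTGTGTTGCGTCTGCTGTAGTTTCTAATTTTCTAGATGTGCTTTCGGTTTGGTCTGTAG, and that of TC286836 reads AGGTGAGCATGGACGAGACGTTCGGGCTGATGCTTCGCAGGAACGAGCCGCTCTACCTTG. These signs are opposite to those of the authors' value table, whose columns run as aerated over waterlogged. At least a 2-fold change was reached by 426 of the called probes, 202 risen and 224 fallen. A group of 15 probes was well above background on all 6 arrays in waterlogged RNA and on none in aerated RNA, and 13 of them were called. The reverse held for 108 probes, of which 54 were called. With the undetected RNA set to the lowest level well above background, median folds were 1.64 for the 15 and 1.26 for the 108. Many of these probes thus lay near the detection limit. In the waterlogged RNA of the second comparison, 8 of the 15 were again well above background on all 6 arrays, and 39 of the 108 were again so on none. In replicate 3 of the first comparison 24.4% of probes were well above background in waterlogged RNA and 33.0% in aerated RNA.

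The count for waterlogging fell most without replicate 3. The fitted changes then had an SD across probes of 0.454, against 0.447 with all, 0.413 without replicate 1 and 0.510 without replicate 2. Means of fewer replicates hold more noise, so these SDs cannot tell whether the changes were smaller. The count was 148 without replicate 3, 1195 without replicate 1 and 2103 without replicate 2. Each of these settings dropped that number from both comparisons, which also left fewer residual degrees of freedom for the shared spread. It was 355 (97 risen, 258 fallen) with median centring and 1218 (152 risen, 1066 fallen) with centring on spike-in controls. The spike-in shift came from replicate 3 (log2 0.80), with 0.05 and -0.06 in replicates 1 and 2. Slide as a random block, which counts an array and its swap separately, gave 6020. The slides that held both comparisons leave 1 waterlogging replicate, and the other slides gave 219.

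The second comparison asked which transcripts differ when ethylene perception is blocked before waterlogging. With 1-MCP 4737 probes changed, 2413 upward and 2324 downward (limma, Benjamini-Hochberg), and 1173 of them changed at least 2-fold. The probe of TC288876 rose 96.6-fold (log2 6.59 ± 0.71, SD, n = 3; limma adjusted p = 2.19e-05) and that of TC299182 rose 74.4-fold (6.22 ± 0.87, SD, n = 3; limma adjusted p = 4.06e-05). With waterlogging their log2 ratios were -2.64 and -2.23 (limma adjusted p = 0.00186 and 0.00539), and the fall of TC299182 was not called without replicate 3 (limma adjusted p = 0.0669). Neither fall was called with scaling between arrays (log2 -4.026 and -4.001; limma adjusted p = 0.0648 and 0.0835) or within the slides that held both comparisons (-2.45 and -2.44; limma adjusted p = 0.074 and 0.0982), where waterlogging has 1 replicate. The probe of TC292792 fell 239.7-fold (log2 -7.90 ± 0.73, SD, n = 3; limma adjusted p = 2.91e-05) and that of TC282787 fell 90.8-fold (-6.50 ± 0.13, SD, n = 3; limma adjusted p = 3.06e-05). Neither passed the test with waterlogging, where their log2 ratios were 0.20 ± 0.78 and 0.21 ± 0.87 (SD, n = 3; limma adjusted p = 0.689 and 0.611), though TC282787 was called upward without replicate 1 (log2 0.71; limma adjusted p = 0.0149). The 60-base probe of TC288876 reads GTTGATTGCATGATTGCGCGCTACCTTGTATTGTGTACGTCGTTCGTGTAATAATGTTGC, and that of TC292792 reads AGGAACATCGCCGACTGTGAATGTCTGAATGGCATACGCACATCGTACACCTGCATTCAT. Well above background on all 6 arrays with 1-MCP and on none in waterlogged RNA were 247 probes, 200 of them called, and the reverse held for 104 probes, 101 of them called. With the undetected RNA set to the lowest level well above background, median folds were 1.40 for the 247 and 1.62 for the 104. Many of these probes thus lay near the detection limit.

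The count for 1-MCP was 2553 without replicate 3 and 7473 with slide as a random block. All 1-MCP arrays lay on the slides that held both comparisons. Restriction to those slides thus dropped no 1-MCP array and cannot test slides for this comparison. Median centring called 2443 (1779 risen, 664 fallen) and centring on spike-in controls 2271 (1818 risen, 453 fallen). The spike-in shift with 1-MCP was largest in replicate 3 (log2 -0.61, against -0.13 and -0.18 in replicates 1 and 2).

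**Figure D1:**
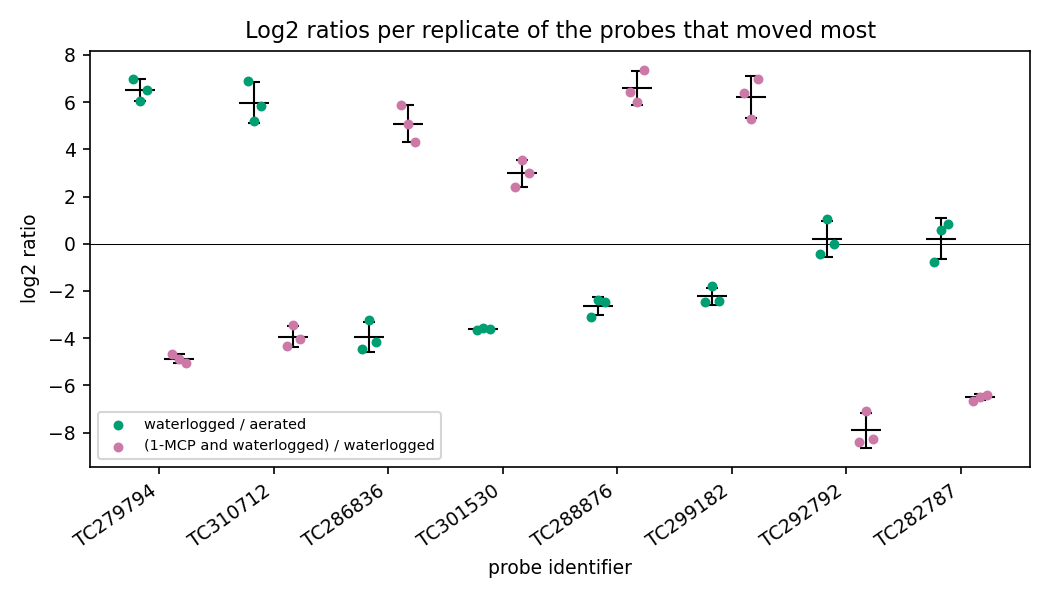
Log2 ratios (vertical axis) of the 8 probes named for the largest rises and falls, with 1 point per replicate (n = 3) and bars for mean and SD, for waterlogged over aerated and for 1-MCP and waterlogged over waterlogged. TC279794 lies at 6.52 with waterlogging and -4.87 with 1-MCP, while TC292792 lies at 0.20 and -7.90.

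Probes changed by waterlogging mostly changed back with 1-MCP where they were called there. Of the 1195 probes that rose with waterlogging, 691 fell with 1-MCP (57.8%), 30 rose and 474 were not called. Of the 1499 that fell, 768 rose with 1-MCP (51.2%), 91 fell and 640 were not called. TC279794 fell by 4.87 and TC310712 fell by 3.94 on the log2 scale with 1-MCP (limma adjusted p = 1.60e-05 and 0.00017). TC286836 rose by 5.08 and TC301530 by 2.98 (limma adjusted p = 8.94e-05 and 8.98e-05). These 4 reversals were not called with scaling between arrays (limma adjusted p = 0.13 to 0.574), where their log2 ratios were -4.03, -3.25, 4.19 and 2.47. Opposite signs were found in 1459 probes and equal signs in 121. Independent lists would share 213 and 278 probes in the opposite directions, and 221 and 268 in the equal ones. In 100 simulations of unchanged groups that shared the waterlogged RNA, the mean number with opposite signs was 0.01, but these called only 0.07 probes with waterlogging and 0.13 with 1-MCP on average, so that an overlap near 0 followed from the few calls. Across probes the fitted changes correlated at r = -0.54, against a simulated -0.50, and their covariance was -0.160, against a simulated -0.00821. Part of the excess over independent lists may still come from the shared waterlogged RNA.

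The count of probes with opposite signs was 122 without replicate 3, 821 without replicate 1 and 957 without replicate 2. It was 249 with median centring (60 risen and 189 fallen with waterlogging), 711 with centring on spike-ins (85 and 626, against 691 and 768), 3267 with slide as a random block and 186 within the slides that held both comparisons.

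**Figure D2:**
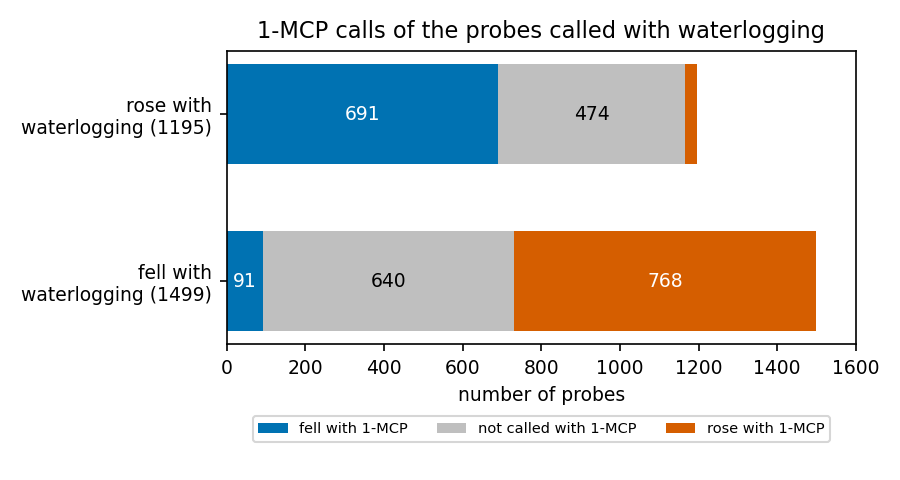
Number of probes (horizontal axis) that rose or fell with waterlogging, divided by their call with 1-MCP. Of the 1195 risen probes 691 fell with 1-MCP, and of the 1499 fallen probes 768 rose.

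**Figure D3:**
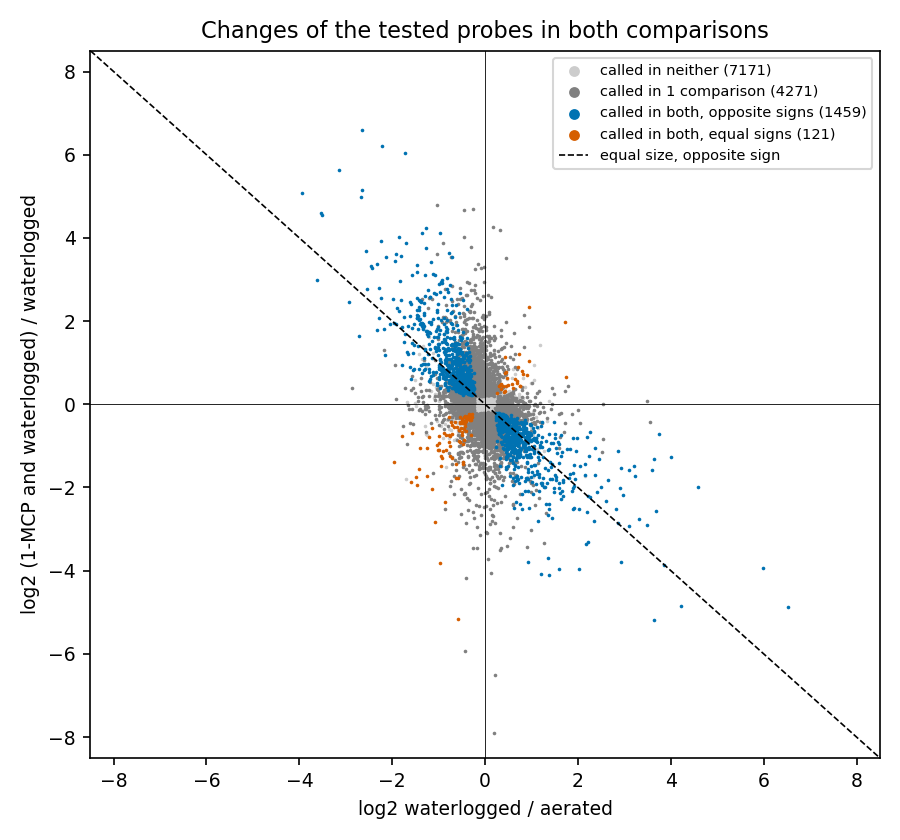
Log2 change with 1-MCP (vertical axis) against log2 change with waterlogging (horizontal axis), 1 point per tested probe, coloured by call, with a dashed line where both changes have equal size and opposite sign. The 1459 probes called with opposite signs lie where the changes differ in sign, at upper left and lower right.

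The indirect contrast set 1-MCP-treated waterlogged roots against aerated roots. It called 1863 probes, 872 above and 991 below the aerated level (limma, Benjamini-Hochberg). Of the 691 probes that rose with waterlogging and fell with 1-MCP, 583 were not called against aerated, 87 lay below it and 21 above. Of the 768 that fell and rose again, 623 were not called, 142 lay above and 3 below. The sum had a larger SE (median 0.132, against 0.093 in each comparison), and these probes were chosen for opposite signs. A probe not called is therefore not shown to have returned to the aerated level. By this sum TC279794 lay 3.13-fold above the aerated level (limma adjusted p = 0.00832), and the log2 difference of TC286836 was 1.13 ± 0.45 (SE; limma adjusted p = 0.141). TC288876 lay 15.5-fold above aerated (limma adjusted p = 0.00228), and TC292792 lay 209-fold below (limma adjusted p = 0.000978). Without replicate 3 these 3 were not called (limma adjusted p = 0.108 for TC279794, and 0.0506 for TC288876 and for TC292792), with log2 differences of 1.73, 3.46 and -7.43. The sum takes the waterlogged RNA as equal in both comparisons, but its channel level across arrays differed in 1300 probes (limma, Benjamini-Hochberg). For these 3 it differed by 1.33, -2.78 and -1.66 (log2; limma adjusted p = 0.111, 0.00364 and 0.0274). Channel levels across arrays can also carry effects of slide, array and partner RNA. These cannot be told here from a difference of the waterlogged RNA itself. With the 1-MCP and aerated channels set against each other across arrays, TC279794 was not called (1.25-fold; limma adjusted p = 0.675), TC288876 lay 106-fold above and TC292792 66.1-fold below (limma adjusted p = 1.72e-06 and 6.88e-06), so the folds are uncertain. Another 3157 probes changed with 1-MCP and were not called with waterlogging. Of these, 577 lay above and 607 below the aerated level. The probes that rose in both comparisons numbered 30 and those that fell in both 91.

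The indirect count was 1 without replicate 3, 1095 without replicate 1 and 886 without replicate 2. It was 328 with median centring (192 above, 136 below), 609 with centring on spike-ins and 3883 with channels set against each other across arrays. Slide as a random block, which counts an array and its swap separately, gave 4703. Slide as a fixed term and the slides that held both comparisons each leave 1 waterlogging replicate. These 2 settings therefore cannot tell a slide effect from that replicate.

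Few probes carry gene names. ZMATP70 was called with waterlogging (log2 0.41 ± 0.23, SD, n = 3; limma adjusted p = 0.048) and not with 1-MCP (-0.31 ± 0.23, SD, n = 3; limma adjusted p = 0.0758). With 1-MCP it was called with eBayes with trend and robust (limma adjusted p = 0.0379) and with slide as a random block (0.00676). Its waterlogging call was lost in 16 of 24 alternatives. In some of these its log2 ratio stayed near 0.41, as without background subtraction (0.42; limma adjusted p = 0.0565) and with the replicate number as a block (0.41; limma adjusted p = 0.0536). In others it was smaller, as with median centring (0.22) and colour swaps alone (0.15). With centring on spike-ins its log2 ratios were 0.10 and 0.03. The probe for ZmSMC3, a subunit of the cohesin complex, had log2 ratios of -0.10 ± 0.05 and -0.05 ± 0.05 (SD, n = 3; limma adjusted p = 0.292 and 0.558). The tested probe of MuDR, a maize transposable element, had log2 ratios of 0.13 ± 0.07 and -0.04 ± 0.09 (SD, n = 3; limma adjusted p = 0.204 and 0.707). With waterlogging it was called with Agilent's processed signals and in the authors' value table (log2 0.56; limma adjusted p = 0.0405 in each), and with slide as a random block (0.13; limma adjusted p = 0.0473). AI676903, listed as LOC100279569 in the gene table, had -0.18 ± 0.10 and -0.11 ± 0.12 (SD, n = 3; limma adjusted p = 0.14 and 0.331), and was called with waterlogging with slide as a random block (log2 -0.18; limma adjusted p = 0.0256).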

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

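The tests of shared waterlogged RNA error, of GC content and signal without loess, of slides, of the spread as the whole cause and of the spike-ins were chosen only after the results were seen. A check of 36 groups of 6 arrays looked for an array far from the rest. A 5% rate would give about 1.8, but it takes the 6 arrays as independent, which an array and its swap are not. In this check 2 stood out. Both were the colour swap of waterlogged against aerated replicate 2: TC279794 read 5.54 there against 6.52 to 7.03 on the other arrays (gap over range 0.655), and TC286836 read -2.24 against -4.51 to -4.11 (gap over range 0.822). That array's log2 ratios had an SD of 0.295, against 0.516 on its first-orientation partner. Without it, 3642 probes were called with waterlogging, 4584 with 1-MCP, 2004 in the indirect contrast and 1736 with opposite signs.

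Changes in the comparisons ran opposite (r = -0.54 across probes). Error of a shared waterlogged extract would act within replicate numbers, yet the mean covariance over the 6 pairs of different numbers was -0.159 (SD 0.0288). Over the 6 pairs that share no slide it was also -0.159 (SD 0.0332), which argues against a bias of shared slides. After loess, smooth trends on GC content and signal of the probes held at most 1.50% of the variance, so their removal moved little. Without loess the trend on signal held up to 27.6% and that on GC content up to 2.03%, and after their removal the highest of 9 correlations was -0.374 (before, -0.284), which argues against smooth trends on those properties. A single waterlogged pool behind all replicates would escape the covariance tests, though the labels name 3 biological replicates. An effect of the 1-MCP treatment, which the design names, stays open and was not tested apart from these values.

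More probes were called with 1-MCP (4737) than with waterlogging (2694). The median SD between replicates was smaller with 1-MCP (ratio 0.813), which is consistent with part of the gap, and with each comparison fitted alone the counts were 4731 and 1519. The spread as the whole cause is argued against: with 1 shared spread per probe 1-MCP still had 1.76 times the calls. Over the alternatives with shared spread and equal n this ratio ran from 1.24 (slide as a random block) to 17.25 (without replicate 3). It was 1.26 without the colour swap of waterlogged against aerated replicate 2. First orientations alone gave 1.26 and colour swaps alone 5.42. The size of the ratio is therefore uncertain and moved with that array. The 1 waterlogging replicate on the slides of the 1-MCP arrays had log2 ratios with an SD of 0.495, inside the range of the other waterlogging replicates (0.382 and 0.597) and below the 1-MCP replicates (0.783, 0.638 and 0.672), which goes against slides, though a single replicate does not exclude them. An effect of 1-MCP apart from waterlogging stays open and untested, as no aerated roots with 1-MCP were measured.

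The 10 spike-in control probes, outside the comparisons, lay above the median tested probe by 0.80 (log2) in waterlogged over aerated replicate 3, and at -0.61 in 1-MCP over waterlogged replicate 3, both of which place them higher in the waterlogged RNA. Replicates 1 and 2 read 0.05 and -0.06 with waterlogging, so waterlogging itself is argued against (replicate 2, -0.059). Slides are argued against too, since 1-MCP replicates 1 and 2, on the same slides, shifted by at most 0.178. A lower yield of labelled messenger RNA in waterlogged replicate 3 stays open, whether or not 1 extract served both comparisons: its share of probes well above background was the lowest by 3.82 percentage points in the first comparison, where its 2 arrays differed by 0.493, but by 0.301 in the second, where they differed by 3.41. No biological explanation was tested.

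For the counts of single contrasts the splits are too few to give a share under 0.05: with waterlogging 1 of 4 sign patterns gave as many (2694, the others at most 0), with 1-MCP 1 of 4 (4737, at most 0), and in the indirect contrast 1 of 10 splits (1863, at most 0). For opposite signs, 1 of 32 sign patterns gave as many (1459, the others at most 121), but turning single replicates ended the calls, so that only the pattern with a whole comparison turned (121) bears on the signs, and with a shared waterlogged extract the 6 ratios would not be independent.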

How the results depend on the processing

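Centring on spike-ins, normexp with offset 10, leaving out 1 colour swap and channels across arrays were chosen after seeing the data. Counts are given in the order waterlogging, 1-MCP, indirect contrast, opposite signs, and the cause of a shift was not tested unless named. Of the alternatives, 14 of 25, 18 of 24, 12 of 25 and 14 of 24 stayed within 1.5 times the reported counts. The 12 include slide as a fixed term, which rests on 1 waterlogging replicate and counts arrays and swaps separately. The 18 include the slides holding both comparisons, a setting that drops no 1-MCP array. Median centring gave 355, 2443, 328 and 249, and scaling between arrays 1765, 2650, 562 and 706. Centring on spike-ins gave 1218, 2271, 609 and 711, with 12.5% of waterlogging calls and 80.1% of 1-MCP calls upward. It put the median of tested probes at -0.27 and 0.29 (log2), median centring at -0.14 and 0.13, and loess at -0.03 and 0.01. The spike-in shifts were largest in replicate 3, at 0.80 with waterlogging and -0.61 with 1-MCP. Replicates 1 and 2 read 0.05 and -0.06 with waterlogging and -0.13 and -0.18 with 1-MCP. A 2-fold minimum, stricter by construction, gave 426, 1173, 751 and 255. Slide as a random block, which counts arrays and swaps separately, gave 6020, 7473, 4703 and 3267. Within the slides holding both comparisons, with fewer replicates, waterlogging gave 244, the indirect contrast 170 and opposite signs 186, and the other slides gave 219 for waterlogging. Colour swaps alone gave 745 (waterlogging), 1138 (indirect) and 541 (opposite). Fitting each comparison alone gave 1519 for waterlogging. For the indirect contrast, 12 arrays with a dye term gave 2795 eBayes with trend and robust 1222, and 1-MCP and aerated channels set against each other across arrays 3883, of which 1456 were among the reported calls. Leaving out a replicate number from both comparisons, with fewer samples, gave 148 to 2103, 2553 to 3772, 1 to 1095 and 122 to 957.

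Whether equal replicate numbers pair the comparisons stays open. Deviations of the same number correlated at only 0.08, 0.03 and 0.05, though 4 of 6 replicates correlated best with their own number. The spike-ins stood apart in waterlogged replicate 3 of both comparisons. With the replicate number as a block, the counts were 2288, 4389, 1507 and 1339; separate channels without pairing gave 2714, 4765, 1787 and 1398.

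Over 654 combinations of a named probe, a comparison and an alternative, 614 kept their side of the threshold. Of the rest, 33 lost a call, 7 gained one and 0 reversed, with no called value turning sign. The combinations include TC293679 and TC289094, which are not described above. The TC probes described above were chosen for large changes with 1 sign on all arrays of a comparison. For that comparison, single orientations or fewer replicates could not reverse these changes. Some alternatives were near duplicates, such as Agilent's processed signals and the authors' value table. The 614 is therefore not independent evidence that the results hold. The gene list alternatives were not run, as no list matched an identifier. Signal over background limited the tests to 13022 of 42034 probes.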

Other observations

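The size of the reversal was measured on replicates other than those that chose the probes. Probes at least 2-fold up with waterlogging in 1 replicate were read for waterlogging in another and for 1-MCP in the remaining number, in all 6 arrangements. Their mean log2 ratio was 1.38 with waterlogging and -1.17 with 1-MCP, a ratio of these means of 84.9% in size (76.8% to 102.7% in single arrangements). Probes at least 2-fold down averaged -1.17 with waterlogging and 1.11 with 1-MCP, a ratio of 94.5% (82.2% to 136.9%). The difference between the directions was not tested.

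Named probes of chromosome cohesion and meiosis were mostly dim in these cortex cells, as were most probes of the array, where 29012 of 42034 were not tested. None of the 7 probes of ZmRAD21, the 2 of ZmSMC1, the 3 of AM1 or the 1 of ZmSGO1 was bright enough to be tested, and 1 of the 4 probes of ZmSMC3 was. Of the 4 MuDR probes 1 was tested.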
